A study of Drosophila melanogaster with 17 samples.

How the data were processed

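Adult whole brains of Drosophila melanogaster were measured on 17 Affymetrix Drosophila genome arrays, 4 brains of both sexes per array. Per the labels, total RNA was prepared with Ambion RNAqueous Micro, amplified with the NuGEN Ovation FFPE WTA system and labelled with NuGEN Encore Biotin. The log2 probe set signals were made by the authors with RMA over all arrays, per the file headers, with affy, RMA and limma named in the labels; their versions are not given in the sources used here. The unfiltered table held 18769 probe sets that were not controls. The series matrix left out 5479 of these by a rule not given in the sources used here, and its remaining values matched the unfiltered table to within 0.0050. The mean signal had a median of 7.91 inside the series matrix and 4.04 outside it, on the log2 scale. Signals near the floor of the arrays, such as 2.17 for moody in its null mutant, were taken as close to background, so folds from or to dim signals are approximate. All main results used the series matrix without further normalization. Array medians lay between 7.856 and 7.991, and correlations between arrays of a group between 0.9742 and 0.9967.

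Of the probe sets, 10243 carried 1 gene symbol, 310 several and 2737 none in the platform annotation, which gave 8938 genes, 840 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean over all arrays, and other probe sets were compared with it. The gene IDs of 10188 probe sets were found in the current annotation of the genome, and 0 symbols changed.

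Groups were taken from the labels: C17, PMdr65, WT_new and UAS_control with 3 arrays and WT_old with 5. Group means were fitted with limma 3.58.1 in R 4.3.3 over all 17 arrays (12 residual and 2.93 prior degrees of freedom, no trend, prior not robust), and 10 contrasts were taken, namely each mutant against each control group, C17 against PMdr65 and the control groups against each other. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. A gene was counted against all 3 control groups when it passed in 1 direction in the 3 contrasts. Levels of moody and Mdr65 were compared by exact permutation of the arrays. Contrasts, tests, gene lists and alternatives were fixed before the data were examined, except where a choice is named as made later.

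The rule for named genes was as follows. It took moody and Mdr65, and, for each mutant, the 12 higher and 12 lower genes with the largest smallest change against the 3 control groups, among those with all mutant arrays beyond all 11 control arrays. It added the 6 higher and 6 lower genes with the largest smallest change in both mutants, the 6 higher and 6 lower with the largest change in each of the contrasts WT_old minus WT_new, UAS_control minus WT_new and C17 minus PMdr65, up to 4 members of each gene list by adjusted p against WT_new, and markers of cell content and sex. Of these markers only Yp1 was named on the table; the others were not analysed here.

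Gene lists covered cell types (neurons, glia, eye, fat body, haemocytes, muscle), the barrier (surface glia, septate junctions, moody G protein signalling), transport and detoxification, stress, immunity, clock, peptides, metabolism, ribosomes, pigment, extracellular matrix and activity-regulated genes. A list of mitochondrially encoded genes had 0 measured members. Lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, and again with an estimated correlation, and adjusted over the lists of a contrast. Members were counted at the threshold over all probe sets and, as a second count, adjusted over the list alone. Fisher's exact test of members called against all 3 control groups was added later, as were tests of the lists without moody and Mdr65. Counts of called septate junction and surface glia members in the unfiltered table, with other normalization or priors, with array weights, or with a replicate block were also added later, as was leaving out WT_new array 3 and UAS_control array 2 together.

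Alternatives were the unfiltered table, a further quantile normalization, centring on array medians, a trended and robust prior, array weights, only the groups compared in the fit, the replicate number as a block, both wild types pooled, the dimmest 40% of probe sets left out, a limit of 2-fold, fry, and each array left out in turn. Other splits of the arrays were counted, all of them or 100 drawn. Outlying arrays were sought in WT_old by the Dixon ratio with a critical value of 0.71. The correlation of the mutants' changes was compared with 50 simulations of unchanged mutants. The model was tested on simulated data, where a log2 change of 1 was found against all 3 control groups in 46 of 50 probe sets. A change of 0.5 was found in 24 of 50 and a change of -1 in 42 of 50, and 1 unchanged probe set was called. Apart from these changes the simulated groups had equal means and independent noise. The real control groups differ from each other, so these numbers do not give the error rates of the rule on the real arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.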

Results

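RNA from whole adult brains of Drosophila melanogaster was measured on 17 Affymetrix arrays in 5 groups. C17 (3 arrays) carried a null allele of moody, a G protein-coupled receptor of the surface glia that seals the blood-brain barrier of the fly. PMdr65 (3 arrays) carried a null allele of Mdr65, an ABC efflux transporter of the same barrier. The controls were 2 sets of Canton S wild type, WT_new (3 arrays) and WT_old (5 arrays), and UAS_control (3 arrays), a line carrying a UAS construct for RNA interference against Mdr65, with a genetic background that the series describes as similar to that of the mutants. The labels name no driver for this line, so it was taken, as in the series, as a control without knockdown; its Mdr65 signal was 10.78 ± 0.18 on the log2 scale, against 10.23 in WT_new and 9.80 in WT_old. Each array held RNA of 4 brains from both sexes, and the values are RMA-normalised log2 signals. The series compared each mutant with WT_new, which was processed on another day, and used WT_old against batch-dependent genes and UAS_control against background. A gene was therefore taken as changed in a mutant where limma called it at an adjusted p under 0.05 in one direction against all 3 control groups. Each null allele was measured in a single line. This rule therefore cannot tell an effect of the allele from other variants of its line. The labels do not say that the arrays of a group came from separate cultures of flies, so the p-values measure the spread between these arrays, whose number limits the precision.

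The targeted transcript was nearly absent in each mutant. The log2 signal of moody was 2.17 ± 0.11 (mean ± SD, n = 3) in C17, against 9.65 to 11.42 on the 14 other arrays (exact two-sided permutation test, p = 0.0015). Mdr65 was at 4.69 ± 0.04 (n = 3) in PMdr65 and between 9.35 and 11.23 on the other 14 arrays (exact two-sided permutation test, p = 0.0015). Each transcript was also at its highest in the mutant of the other gene. In PMdr65, moody stood at 11.39 ± 0.04, above all 11 control arrays, which spanned 9.65 to 10.20 (exact permutation test, p = 0.0027). It rose by 1.62 on the log2 scale over WT_new, 1.39 over WT_old and 1.37 over UAS_control (limma, highest adjusted p = 3.26e-07). Mdr65 in C17 was at 11.09 ± 0.14, and its rise of 0.86 over WT_new and 1.29 over WT_old was called, while the difference of 0.31 from UAS_control was not (limma, adjusted p = 0.178).

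**Figure D1:**
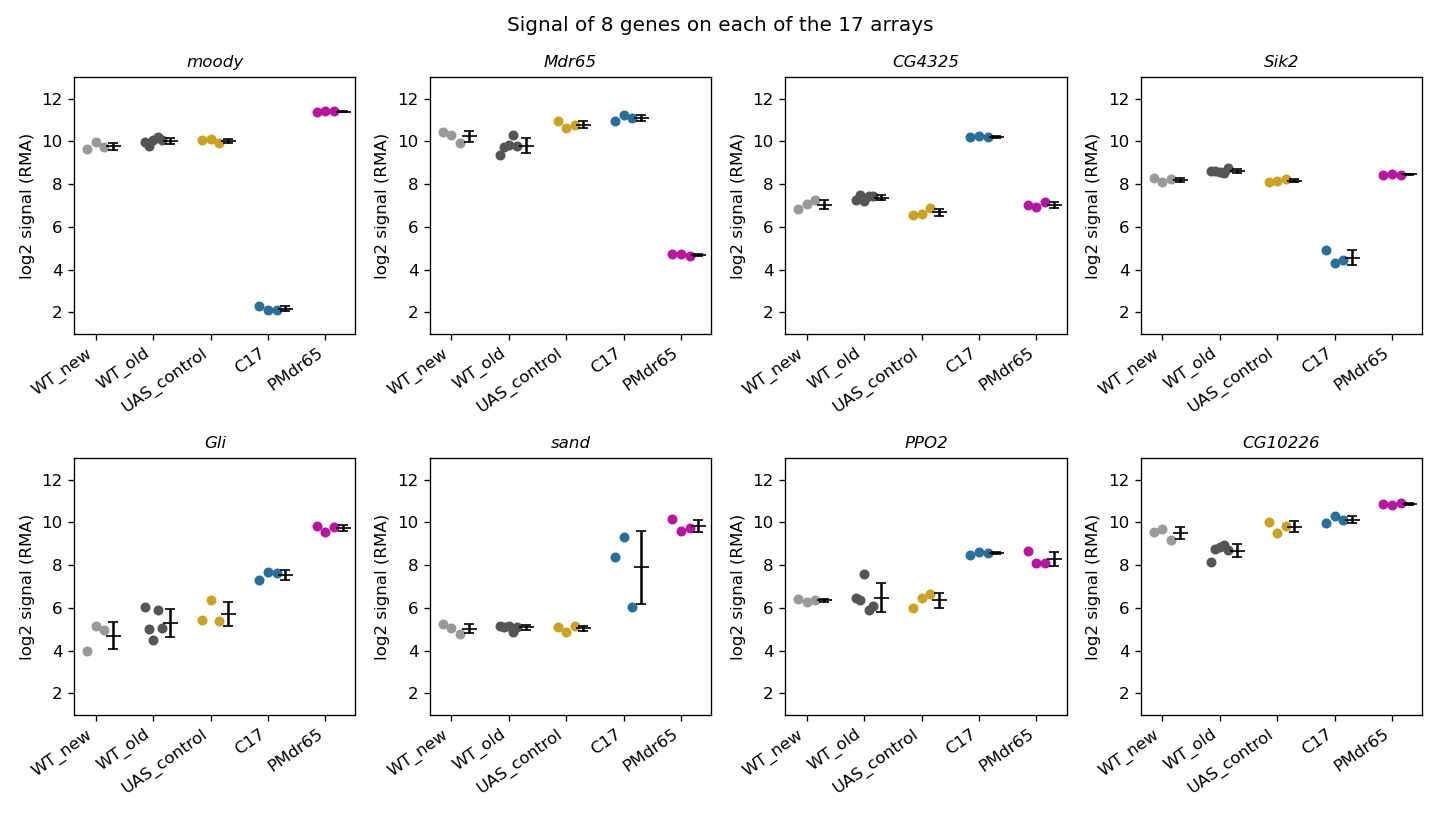
RMA log2 signal of 8 genes (vertical axis) on each of the 17 arrays, arranged by group; each point is 1 array and the black bars give the group mean and SD. The moody signal is near 2.17 in C17 and 11.39 in PMdr65, and Mdr65 is near 4.69 in PMdr65, while Gli, sand and PPO2 lie above the controls in both mutants.

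In the moody null brains, transcripts with strong rises included CG18343, CG4325 and the synaptic adhesion molecule Nlg1, a neuroligin. CG18343 had a log2 signal of 7.02 ± 0.17 (n = 3) in C17 and group means of 3.35 to 4.03 in the controls near the floor of the arrays, a log2 rise of 2.98 to 3.67. CG4325 rose 7.2- to 11.6-fold, from control means of 6.67 to 7.36 to 10.21 ± 0.03. Nlg1 rose from similarly dim means of 3.27 to 3.49 to 5.72 ± 0.31, and Septin5, a cytoskeletal GTPase, rose 3.7- to 7.5-fold. Among the transcripts that fell, Sik2, a salt-inducible kinase, fell by 3.59 to 4.04 on the log2 scale, with 4.57 ± 0.33 in C17 and 8.16 to 8.61 in the controls. Oatp33Ea, an organic anion transporter, was 9.1- to 10.7-fold lower and the cytochrome P450 gene Cyp12a4 5.6- to 8.3-fold lower. The antiviral factor pst (pastrel) was 2.9- to 5.9-fold lower. In each of these genes the 3 C17 arrays lay beyond all 11 control arrays, and the highest adjusted p over the 3 limma contrasts was 4.47e-05. CG4325 and Sik2 are among the 10 measured genes nearest to moody, and an effect of the lesion or of linked background on them stays open.

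Genes named by the same rule in C17 also included CG34002, CG7054, CG13130 and CG4476 among the higher ones, with CG6040, CG6908, CG5835, CG12857, CG4511, CG10257 and Ugt302K1 among the lower ones. Their smallest change over the 3 control groups was 2.8-fold or more. In total 391 genes rose and 203 fell in C17 against all 3 control groups, out of 8938 measured, and in 372 and 187 of them the C17 arrays lay beyond every control array. Chance gives this order in a share of 0.0027 for a gene not chosen by its call, so for called genes the count is a description and no further test. On the level of probe sets the counts were 588 higher and 270 lower. Of these 858 calls, 84 reached 2-fold in all 3 contrasts. Leaving out C17 array 2 lowered the 858 calls to 553.

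In the Mdr65 null brains the largest rises were in Gli, sand and lncRNA:CR32368. Gli encodes gliotactin, a protein of the junctions where 3 septate junctions meet. Its log2 signal was 9.74 ± 0.15 (n = 3) in PMdr65 and 4.70 to 5.72 in the control means, a rise of 16.2- to 32.8-fold (limma, highest adjusted p = 3.87e-06). The two-pore potassium channel gene sand rose 26.6- to 27.8-fold, to 9.83 ± 0.28. Sting, a sensor of the innate immune response, rose 8.4- to 9.3-fold, and Lsp2, a storage protein of the fat body, 4.8- to 18.7-fold. The Lsp2 signal was 9.02 on PMdr65 array 2 and 7.46 and 7.07 on the other PMdr65 arrays. Fat body RNA in the samples was not told apart from a change in the brain for Lsp2. The transporter gene NaPi-T rose 4.4- to 18.5-fold and Cyp9h1, a cytochrome P450, 5.1- to 9.0-fold.

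Of the genes that fell in PMdr65, Ssu72, a phosphatase of the RNA polymerase II tail, was 4.0- to 11.1-fold lower, and its second probe set fell by 3.30 on the log2 scale against WT_new. Ugt35B1, a UDP-glycosyltransferase, fell 2.9- to 3.9-fold from a control level of 11.07 to 11.49. Dhrs4 fell 3.1- to 5.6-fold and the odorant binding protein gene Obp49a 2.7- to 4.1-fold. The muscle actin gene Act79B fell 2.9-fold against WT_old and 12.5-fold against UAS_control, where muscle transcripts were high. Muscle RNA in the samples was not told apart from a change in the brain for this gene. The peptide hormone gene Eh rose by 3.03 to 3.55 on the log2 scale (limma, highest adjusted p = 0.0334), but its control groups had SDs of 1.63 to 2.34, and a trended and robust prior ended the call. The hexokinase gene Hex-C fell 2.0- to 3.3-fold (limma, highest adjusted p = 0.0249), a call lost when a single array was left out. The other genes under the rule were CG33483, CG30187 and CG6602 on the higher side, and Myo28B1, CG12560, CG10550, Menl-2 and CG6908 on the lower side. Against all 3 control groups 525 genes rose and 284 fell in PMdr65, of which 473 and 256 had all PMdr65 arrays beyond the control arrays. These were 735 higher and 374 lower probe sets, of which 71 reached 2-fold in all 3 contrasts.

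In PMdr65 the list with the largest share of members called against all 3 control groups was that of the septate junctions. These are the seals between the glia of the barrier. Of 23 measured members, 12 rose in PMdr65 against all 3 control groups and 0 fell. The count was 13 adjusted over the list alone. Beside Gli, cold rose by 0.91 to 1.51 on the log2 scale, Cont by 0.57 to 0.96 and cora by 0.44 to 0.83. Further members, chosen after their values were seen, were kune (0.60 to 0.68), Nrx-IV (0.40 to 0.68), Lac (0.83 to 1.20), pck (0.40 to 0.95), crok (0.52 to 0.74), Nrg (0.49 to 0.56), Tsf2 and crim. Another probe set of Nrg moved the other way, by -0.20 against WT_new. The share of called members was 52.2%, against 9.1% of all genes (Fisher's exact test, adjusted p = 4.4e-06, chosen after the data were seen). This test takes the members as independent of each other. Camera with an estimated correlation did not call the list in PMdr65 against any of the 3 control groups. The list median was also higher in WT_old than in WT_new.

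In C17 the septate junction members higher against all 3 control groups were 5 of 23, with 0 lower and 7 higher adjusted over the list alone. They were Gli, which rose 3.5- to 7.2-fold to 7.54 ± 0.22 (limma, highest adjusted p = 0.00155), cold (0.65 to 1.25 on the log2 scale), cora, kune and sinu. Only 3 members were called in the unfiltered matrix or after another quantile normalization, counts added after the data were seen, and 3 without C17 array 2, C17 array 3 or WT_old array 2. In the unfiltered matrix kune against UAS_control and sinu against WT_old lost their limma calls, so these 2 are not secure. Fisher's exact test of the 5 members gave an adjusted p of 0.095. In the direct contrast 0 members were higher and 5 lower in C17 than in PMdr65 (12 lower adjusted over the list alone), with a median of -0.2 (camera, adjusted p = 6.9e-07; adjusted p = 0.068 with an estimated correlation). For Gli the log2 fold change of C17 against PMdr65 was -2.20 (limma, adjusted p = 0.00175).

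**Figure D2:**
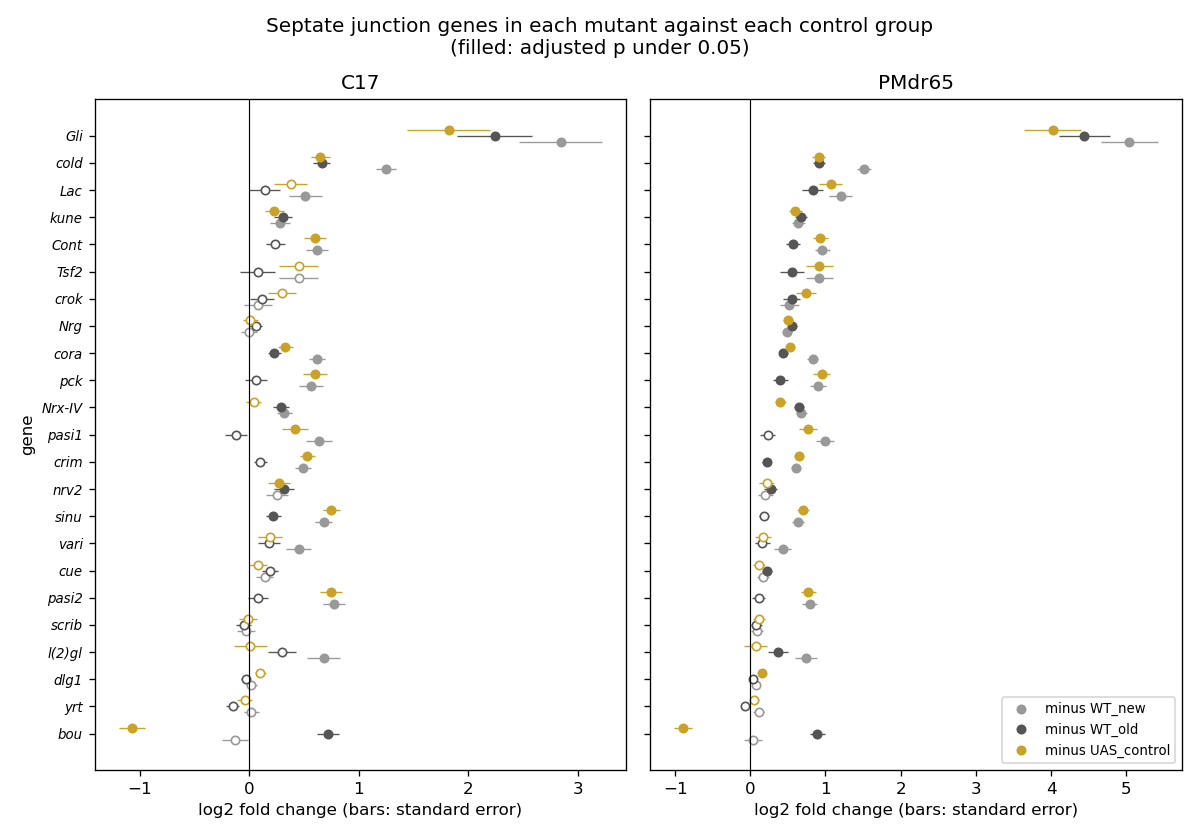
Log2 fold change (horizontal axis, bars give the limma standard error) of the 23 septate junction genes in C17 and PMdr65 against WT_new, WT_old and UAS_control; filled points have an adjusted p under 0.05. In PMdr65, 12 genes were higher against every control group, with Gli at 4.02 to 5.04, and in C17 5 genes were.

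Of 21 markers of the surface glia, 8 rose and 1, Mdr65 itself, fell in PMdr65 against all 3 control groups, with the same counts adjusted over the list alone. They included moody, ltl (0.81 to 1.30 on the log2 scale), CG10226, an ABC transporter gene beside Mdr65 (2.1- to 4.5-fold), PRL-1 (0.28 to 0.57) and the lipophorin receptor genes LpR1 and LpR2. The others that rose, Gli and Lac, are also in the septate junction list. Fisher's exact tests of both lists therefore count some of the same genes. The called share was 42.9% (Fisher's exact test, adjusted p = 0.00063), and without moody and Mdr65 it was 36.8%, or 7 of 19 (adjusted p = 0.014, chosen after the data were seen). In C17, 5 rose, namely Gli, ltl (0.67 to 1.16), PRL-1 (0.45 to 0.74), LpR1 (0.23 to 0.34) and CG3168, and 1, moody, fell (5 higher and 2 lower adjusted over the list alone; Fisher's exact test, adjusted p = 0.058, and 0.11 without moody and Mdr65). The list as a whole was higher against WT_old, with 15 higher and 1 lower member in each mutant, but camera did not call it against the other controls. The test fry called it higher against WT_new in PMdr65 (fry, adjusted p = 0.0094) but lower in C17 against WT_new (0.0082) and UAS_control (fry, adjusted p = 0.0002), and did not call it in C17 against WT_old (fry, adjusted p = 0.41). The list holds moody and Mdr65, each nearly absent in its own null mutant, and fry was not run without them. These fry values therefore cannot decide the direction of the other members, which is open in C17. The camera adjusted p against WT_old was 1.9e-05 in C17 and 1.2e-07 in PMdr65, and 0.58 and 0.17 as adjusted p with an estimated correlation. WT_old itself was low for this list, with 12 of 21 members lower than in WT_new (camera, adjusted p = 0.011; adjusted p = 0.42 with an estimated correlation) and 13 higher in UAS_control than in WT_old (camera, adjusted p = 0.0007; adjusted p = 0.33 with an estimated correlation). In the wider glia list of 19 genes, 5 rose in PMdr65 (moody, Gli, ltl, drpr and wrapper; 5 adjusted over the list alone) and 3 rose and 2 fell in C17 (5 and 2 adjusted over the list alone). Of 6 members of the moody G protein pathway, moody and Galphai rose in PMdr65 and moody fell in C17, with the same counts adjusted over the list alone. The rise of Galphai, 0.33 to 0.40, was lost without WT_new array 3 and UAS_control array 2.

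Of the transport and detoxification lists in this paragraph none passed Fisher's exact test of members called against all 3 control groups, chosen after the data were seen. The lowest adjusted p of Fisher's exact test was 0.095 in C17, for organic anion and cation transporters, and 0.13 in PMdr65, for cytochrome P450 genes. Of 65 cytochrome P450 genes, 4 rose and 2 fell in C17 (4 and 3 adjusted over the list alone), and 7 rose and 5 fell in PMdr65 (7 and 5 adjusted over the list alone). Cyp6a13 rose 2.4- to 2.8-fold in C17 and 2.1- to 2.4-fold in PMdr65 (limma, highest adjusted p = 5.07e-06), Cyp12a5 2.3- to 4.1-fold in C17 and Cyp28d1 fell 1.5- to 2.1-fold in PMdr65. Of 27 glutathione S-transferase genes, 3 rose and 2 fell in C17 (2 and 1 adjusted over the list alone), and 4 rose and 2 fell in PMdr65 (4 and 1 adjusted over the list alone). GstE1 rose 1.4- to 2.5-fold and GstD9 fell 1.5- to 2.0-fold in C17, and GstS1 rose 1.9- to 2.4-fold in PMdr65. Among 30 UDP-glycosyltransferases and related enzymes the counts were 1 higher and 2 lower in C17 (the same adjusted over the list alone) and 0 higher and 3 lower in PMdr65 (1 and 3 adjusted over the list alone), with Ugt35B1 lower in both. Of 38 ABC transporter genes, Abca3 and Atet rose by 0.21 to 0.64 in both mutants, a size at which several other settings lost the call. The total was 3 higher in C17 and 3 higher and 1 lower in PMdr65, the same adjusted over the list alone. Among 15 organic anion and cation transporters 3 rose and 1, Oatp33Ea, fell in C17, and 2 rose and 1 fell in PMdr65, also the same adjusted over the list alone. Oatp74D rose 1.6- to 3.1-fold in C17.

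Of 27 pan-neuronal and transmitter genes, 1 rose and 1 fell in C17, and 3 rose and 1 fell in PMdr65 (1 and 1, and 2 and 1, adjusted over the list alone). The called shares were 7.4% and 14.8%, against 6.6% and 9.1% of all genes (Fisher's exact test, adjusted p = 0.96 and 0.67). Of 13 clock genes, tim rose in both mutants, 2.0- to 3.7-fold in C17 and 2.0- to 3.6-fold in PMdr65 (limma, highest adjusted p = 9.49e-06), and its other probe set rose by 1.16 to 1.84. Pdf, the peptide of the clock neurons, rose 2.0- to 2.4-fold in C17, to 11.25 ± 0.13 (limma, highest adjusted p = 4.84e-05), and stood at 9.96 ± 0.12 in PMdr65, with a log2 difference of 1.29 between the mutants (limma, adjusted p = 1.46e-05). The clock list held 2 higher genes in C17 (3 adjusted over the list alone) and 1 in PMdr65. Of 27 neuropeptide and insulin-like peptide genes, 4 rose and 2 fell in C17 (6 and 2 adjusted over the list alone), and 4 rose in PMdr65 (4 adjusted over the list alone). In C17 these were 22.2% of the peptide genes, against 6.6% of all genes (Fisher's exact test, adjusted p = 0.075). SIFa fell 1.7- to 2.6-fold in C17, and Ilp5 rose 1.7- to 5.4-fold in PMdr65 (limma, highest adjusted p = 0.0014).

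No metabolic, stress or other list of this paragraph passed Fisher's exact test for its share of calls against all 3 control groups. The lowest adjusted p was 0.2, for oxidative stress genes in C17 (19% against 6.6% of all genes). Of 64 oxidative phosphorylation genes, UQCR-11 rose 2.0- to 2.6-fold and ND-B14.7 and ND-PDSW fell 1.3- to 2.1-fold in both mutants. Of 29 sugar transport and glycolysis genes, 3 rose in C17, with sut3 at 3.89 ± 0.55 and at a floor level of 2.42 to 2.49 in the controls, and 3 rose and 1 fell in PMdr65 (3, and 4 and 1, adjusted over the list alone). In the lipid list of 31, LpR1 rose in C17, and 4 rose and 1, whd, fell in PMdr65. Acsl, an acyl-CoA synthetase gene, rose 1.4- to 1.6-fold and NLaz, a lipocalin gene, 1.5- to 2.1-fold in PMdr65. Of 21 oxidative stress genes 3 rose and 1 fell in C17, where Prx3 was 1.4- to 1.7-fold lower, and 1 rose and 1 fell in PMdr65. Among the 23 antimicrobial and immune genes PGRP-LB alone was called, higher in both mutants by 0.26 to 0.67. The 13 haemocyte markers gave 1 call in each mutant, the prophenoloxidase gene PPO2, at 8.56 ± 0.07 in C17 and 8.28 ± 0.34 in PMdr65 against 6.36 to 6.48 in the controls. Of 5 Turandot and JAK-STAT genes 1 rose in C17, of 14 heat shock genes 1 in PMdr65, of 18 amino acid transporters 1 in C17 (CG5535, 0.67 to 1.28), of 16 pigment and background genes 1 in PMdr65 (y, 0.61 to 0.90), and of 21 ecdysone response genes 1 rose and 1 fell in each. The one that fell was ftz-f1, whose other probe set was higher against WT_new, by 0.55 in C17 and 0.72 in PMdr65, and against UAS_control, by 0.41 and 0.58, so its direction is open. Of 37 ribosomal protein genes 2 fell in C17 and 1 in PMdr65, and of 23 odorant binding proteins 1 rose and 1 fell in C17 and 1 fell in PMdr65. Of 17 eye genes 1 fell in C17 and 1 rose in PMdr65, of 13 fat body genes 2 rose in PMdr65 (Lsp2 and NLaz), and of 17 muscle genes 1 fell in PMdr65. Adjusted over the list alone, the counts of this paragraph differed for oxidative stress in PMdr65 (1 higher, 2 lower), Turandot genes in C17 (2 higher), ribosomal proteins in C17 (1 lower), odorant binding proteins in C17 (0), ecdysone response in PMdr65 (1 lower), extracellular matrix in C17 (1 lower) and activity-regulated genes in C17 (1 higher). No call was made by limma in either mutant among 14 extracellular matrix and 11 activity-regulated genes, or in C17 among the fat body, muscle and pigment lists.

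Against WT_new alone, which was the main contrast of the series, the calls were far more numerous. In C17, 49 of 64 oxidative phosphorylation genes fell and 4 rose (median -0.35; 50 lower and 4 higher adjusted over the list alone; camera, adjusted p = 8.3e-14; adjusted p = 0.54 with an estimated correlation). In PMdr65, 46 fell and 3 rose (median -0.34; 49 and 4 adjusted over the list alone; adjusted p = 3.7e-11; adjusted p = 0.68 with an estimated correlation). Ribosomal protein genes fell in 19 and 18 of 37 cases (19 and 19 adjusted over the list alone; camera, adjusted p = 8.8e-05 and 0.00046; adjusted p = 0.54 and 0.68 with an estimated correlation). The list fell against UAS_control too, with 51 of 64 members lower in C17 (median -0.36; camera, adjusted p = 5.9e-13; adjusted p = 0.4 with an estimated correlation) and 46 in PMdr65 (median -0.35; camera, adjusted p = 6e-12; adjusted p = 0.5 with an estimated correlation). Against WT_old, itself lower than WT_new in these genes, it turned round, with medians of 0.08 in C17 (camera, adjusted p = 0.021; adjusted p = 0.71 with an estimated correlation) and 0.13 in PMdr65 (camera, adjusted p = 0.0042; adjusted p = 0.65 with an estimated correlation). Septate junction genes were higher in 14 cases in C17 and 17 in PMdr65 (16 and 17 adjusted over the list alone), with medians of 0.45 and 0.64. Their camera adjusted p was 0.00014 and 6.2e-09, and 0.54 and 0.064 as adjusted p with an estimated correlation. The list was higher against WT_old and UAS_control as well, with medians of 0.18 and 0.3 in C17 (camera, adjusted p = 0.0076 and 0.0065; adjusted p = 0.58 and 0.4 with an estimated correlation) and 0.4 and 0.6 in PMdr65 (camera, adjusted p = 4.1e-08 and 1.3e-07; adjusted p = 0.079 and 0.12 with an estimated correlation). It was also higher in WT_old than in WT_new, with 12 members higher, 1 lower and a median of 0.37 (camera, adjusted p = 0.024; adjusted p = 0.42 with an estimated correlation). Of 23 odorant binding protein genes 9 were lower in PMdr65 (9 adjusted over the list alone; camera, adjusted p = 0.017; adjusted p = 0.68 with an estimated correlation). No camera call against WT_new held with an estimated correlation, and camera called no other list there. The test fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, called 27 further lists over the 2 mutants in the direction that camera gave, such as the circadian clock (adjusted p = 8.8e-07) and extracellular matrix (adjusted p = 0.00056) in C17 and oxidative stress in PMdr65 (adjusted p = 0.00065).

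The total against WT_new was 3349 higher and 2100 lower probe sets in C17 and 3181 higher and 2342 lower in PMdr65. Against WT_old the counts were 1373 and 1239 in C17 and 1770 and 2077 in PMdr65. Leaving out C17 array 2 lowered the 2612 calls of C17 against WT_old to 1709. The majority direction against WT_old turned with the scaling, from 46% higher to 53.3% in PMdr65 after centring on array medians and from 52.6% to 49.2% in C17 after another quantile normalization, and at 2-fold PMdr65 had 232 higher and 116 lower. Against UAS_control they were 3487 and 2249 in C17 and 3063 and 2199 in PMdr65, but at 2-fold the lower ones prevailed, with 206 higher and 447 lower in C17 and 123 and 429 in PMdr65. Muscle genes were lower against UAS_control in both mutants (12 of 17 lower in C17, median -1.87, camera adjusted p = 0.00056, and 11 of 17 in PMdr65, median -2.26, adjusted p = 0.00053; adjusted p = 0.56 and 0.58 with an estimated correlation). Muscle transcripts were at their highest on UAS_control array 2. The mutants and WT_new were not processed on 1 day, so batch and group cannot be told apart in that contrast.

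Both mutants shared changes in 316 genes, 216 higher and 100 lower against all 3 control groups. The gene sand, which is dim in the controls at 5.03 to 5.09, reached 7.90 ± 1.70 in C17 and 9.83 ± 0.28 in PMdr65. Its signal was 6.02 on C17 array 3 and 8.37 and 9.33 on the other C17 arrays. PPO2 rose 4.2- to 4.6-fold in C17 and 3.5- to 3.8-fold in PMdr65, the gene flip 4.0- to 5.2-fold and 3.1- to 4.1-fold, and the odorant receptor gene Or45b 2.8- to 3.7-fold and 2.5- to 3.3-fold. CG6602 rose as well, and CG6908, Ugt35B1, CG10550, CG11891, CG8568 and the transcription factor gene retn fell in both. The junction gene Gli is part of this set too. For retn the fall was 2.1- to 4.2-fold in C17 and 1.8- to 3.7-fold in PMdr65. Among the shared genes named here the highest adjusted p over the 6 limma contrasts was 0.00667.

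On the level of probe sets 296 were higher and 130 lower in both mutants (426, or 283 without C17 array 2), and 6 moved in opposite directions. Independent lists of these lengths would share 32.5 higher and 7.6 lower probe sets. Both lists were called against the same control arrays and are not independent, so the excess over these numbers does not measure a shared effect. The fold changes of the 2 mutants correlated across probe sets at r = 0.799 against WT_new, 0.688 against WT_old and 0.845 against UAS_control. Probe sets are not independent replicates. With no effect in any group the shared controls alone gave 0.504, 0.383 and 0.509, and unchanged mutants at the mean of the real control groups gave 0.694 against WT_new and 0.888 against WT_old. The covariance was 0.199, 0.11 and 0.272, beside 0.015, 0.009 and 0.015 simulated. When the 5 WT_old arrays were split so that each mutant had its own, the median over 20 splits was r = 0.619 (covariance 0.103). The covariance of those unchanged mutants was 0.033 against WT_new and 0.116 against WT_old, so the correlation against WT_old is no evidence of a shared effect of the alleles. No value of those unchanged mutants was reported against UAS_control. The correlation and covariance there stand only beside the simulation with no effect in any group, and cannot decide on a shared effect.

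The direct contrast of C17 with PMdr65 had 529 higher and 408 lower probe sets. It was led by the targeted genes and by genes with an on or off pattern over the 5 groups. The receptor gene mthl8 was at 9.09 ± 0.12 in C17 and 3.49 ± 0.15 in PMdr65, with 7.81 ± 0.42 in UAS_control and 3.32 to 3.87 in the wild types. The transcription factor gene NFAT was at 2.95 ± 0.17 in C17 and 7.84 ± 0.32 in PMdr65, with 6.99 ± 0.30 in UAS_control and 2.85 to 2.87 in the wild types. CG11052 and CG16879 were higher in C17 by 3.71 and 4.03 on the log2 scale, and Ssu72 by 3.60. CG16879 was at 9.31 to 9.68 in C17 and 8.79 to 9.68 in the wild types. It was at 5.27 to 5.53 in PMdr65 and 5.18 to 5.6 in UAS_control. CG11052 was also low in both PMdr65 (3.49 to 3.83) and UAS_control (3.74 to 4.49), and lower in C17 than in the wild types. Ssu72 in C17, at 7.45 to 7.58, lay within the wild-type range of 7.03 to 7.68. NaPi-T, Sik2, Oatp33Ea and lncRNA:CR32368 were lower in C17, with log2 fold changes of -3.94, -3.88, -3.29 and -4.17 (limma, highest adjusted p = 1.13e-05). Clock genes were higher in C17 than in PMdr65 in 5 of 13 cases and lower in 1 (median 0.17; camera, adjusted p = 0.0099; adjusted p = 0.068 with an estimated correlation). The count of 937 probe sets fell to 601 to 671 when any 1 of the 6 C17 and PMdr65 arrays was left out, the lowest without C17 array 3, with 617 without C17 array 1 and 612 without PMdr65 array 2. It rose to 1637 in a fit of only the groups compared and to 2335 with array weights.

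The wild-type groups differed from each other in 6035 probe sets. Single heat shock genes were higher in WT_old than in WT_new, Hsp26 9.22-fold, at 10.58 ± 0.49 (n = 5) against 7.37 ± 0.26 (n = 3), and Hsp27 3.65-fold, and the Hsp70 family gene Hsp68 was higher 8.61-fold. The heat shock list of 14 genes, with 7 higher and 3 lower, was not called (camera, adjusted p = 0.08; adjusted p = 0.42 with an estimated correlation). The yolk protein genes, made in the fat body and ovary of females, were far lower in WT_old, with log2 fold changes of -3.93 for Yp1 and -5.29 for Yp3, and Yp2 fell 32.0-fold. Yp1 was at 8.38 ± 0.75 in WT_old and at group means of 11.31 to 12.46 elsewhere. The medians of the 13 fat body genes, which include the yolk protein genes, were -0.68 to -0.45 on the WT_old arrays, with gene means removed. On the WT_new arrays they were -0.07 to 0.69. Of 64 oxidative phosphorylation genes 54 were lower and 5 higher in WT_old (camera, adjusted p = 1.9e-19; adjusted p = 0.42 with an estimated correlation). The other named genes were hry, FASN3 and jumu on the higher side and Nplp3, CG7214 and CG4000 on the lower side (limma, highest adjusted p = 0.000791). In total 3764 probe sets were higher and 2271 lower, and at 2-fold the balance turned, with 73 higher and 219 lower. Days of processing are not given in the sources used here for WT_old and UAS_control.

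UAS_control differed from WT_new in single genes by large factors. The cytochrome P450 gene Cyp6a17 was at 9.25 ± 0.02 in UAS_control and 3.41 ± 0.19 in WT_new, and the mutants, at 9.56 and 9.53, were like UAS_control. The zinc transporter gene Zip102B was the reverse, at 3.95 ± 0.23 in UAS_control, 3.95 and 3.97 in the mutants and 8.86 ± 0.30 in WT_new. Spn43Aa and CG17290 were higher in UAS_control by 4.27 and 4.37 on the log2 scale, and the stress-induced gene TotC by 6.11 with a standard error of 1.34 (limma, adjusted p = 0.00675). GILT3, CG14645 and CG33483 were lower, though CG14645 ranged from 4.96 to 10.49 within WT_new. In total 998 probe sets were higher and 1017 lower (201 and 93 at 2-fold). The count of 2015 fell to 488 in a fit of only these groups and to 1219 without WT_new array 1, and the higher share of 49.5% moved to 39.1% after another quantile normalization. Against WT_old, 2956 probe sets were higher and 4409 lower in UAS_control (607 and 201 at 2-fold), and the oxidative phosphorylation (52 of 64 higher), fat body (11 of 13), muscle (14 of 17) and antimicrobial genes (13 of 23) were called higher as lists (camera, highest adjusted p = 0.0012; adjusted p = 0.33 for each with an estimated correlation).

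Transcripts of other tissues varied between arrays. The photoreceptor arrestin gene Arr2 was at 12.36 on WT_new array 3 and at 8.23 and 9.09 on the other WT_new arrays, at 11.53 to 12.15 on the UAS_control arrays, and below these levels, at 6.47 to 7.94, on all arrays of C17, PMdr65 and WT_old. The muscle myosin gene Mlc2 was at 10.35 on UAS_control array 2 and at 2.88 to 7.67 on the others. The medians of the neuronal genes per array spanned -0.10 to 0.09. Without WT_new array 3 and UAS_control array 2, a choice made after the data were seen, 882 probe sets were called in C17 against all 3 control groups, 744 of them the same as before. For PMdr65 the count was 1109, with 977 the same, and for both mutants 429, with 358 the same. Eye RNA stayed on the other UAS_control arrays in this setting, so these counts do not show independence from it.

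**Figure D3:**
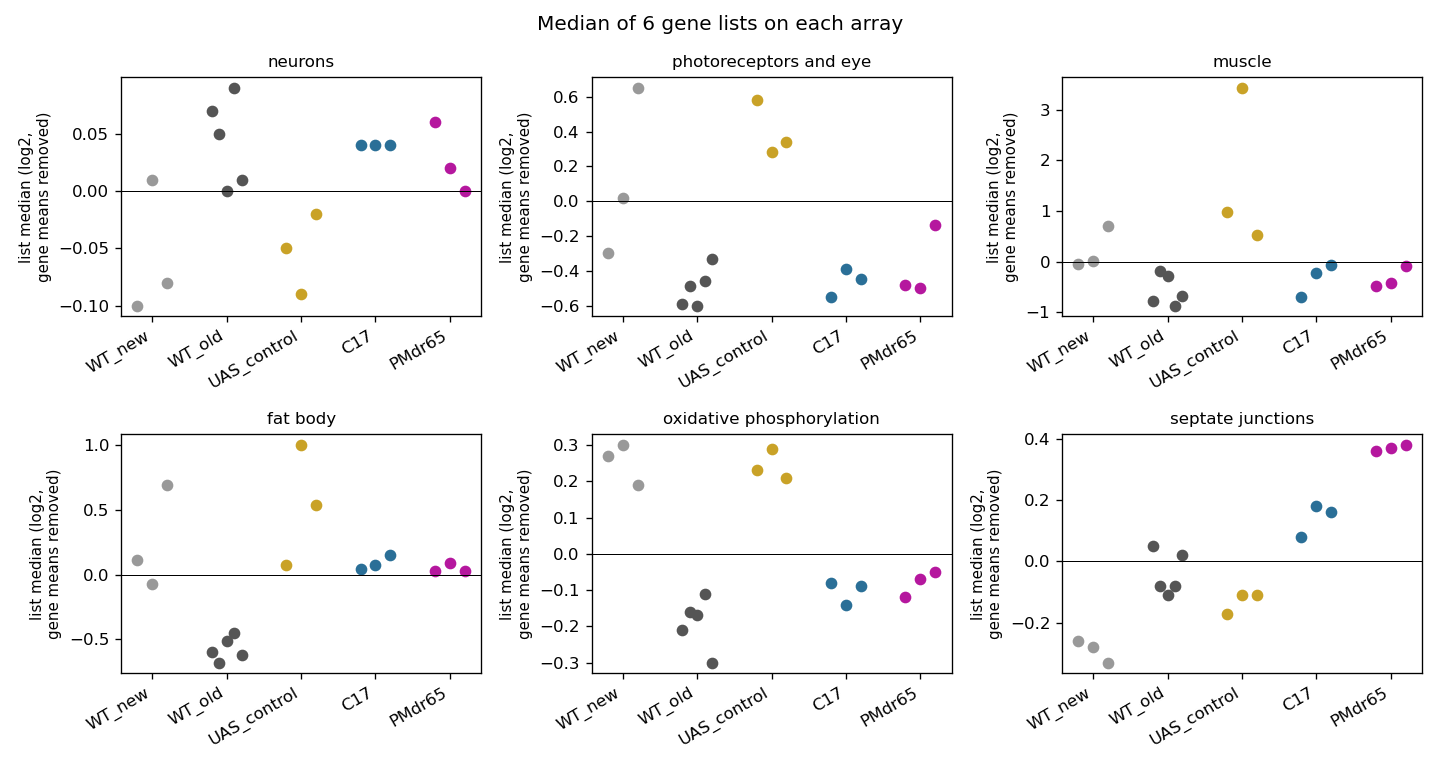
Median log2 signal of 6 gene lists on each of the 17 arrays, after the mean of each gene over all arrays was removed (vertical axis); each point is 1 array. Eye genes are higher on WT_new array 3 and the UAS_control arrays, muscle genes reach 3.43 on UAS_control array 2, and septate junction genes are highest in PMdr65, at 0.36 to 0.38.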

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

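The tests of eye and muscle RNA, of a scaling error, of the wild-type difference without single arrays, of surface glia, of neighbouring genes, of lists without the targeted genes and of other splits were chosen after the results were seen; those of a processing batch, of linked background and of a strain variant were set before.

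Single WT_old arrays lay far from the other 4 of their group in 3 of 71 genes, where the gap exceeded 0.71 of the range. These were sand on array 4 (ratio 0.750; 4.89 against 5.10 to 5.17), TotC on array 1 (0.803; 7.96 against 2.22 to 3.35) and CG16879 on array 5 (0.758; 9.24 against 9.57 to 9.68). Of 30 list medians 0 exceeded it. With 71 genes tested, a few are likely to pass the critical value by chance, so this count is no evidence of an outlying array.

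Gene lists differed between C17 and PMdr65 for glia (median -0.03; camera, adjusted p = 0.032, 0.73 with an estimated correlation), haemocytes (-0.26; 0.015, 0.51), septate junctions (-0.2; 6.9e-07, 0.068), moody G protein signalling (-0.01; 0.032, 0.36), the circadian clock (0.17; 0.0099, 0.068) and extracellular matrix (-0.23; 0.032, 0.36). The glia and moody G protein lists hold moody itself, which the null allele removes in C17, and without it their adjusted p was 0.43 and 0.92, so neither call says more than the lesion. Genes called against all 3 control groups in opposite directions had log2 fold changes between C17 and PMdr65 of 1.65 for Ctr9, 0.96 for CG13685, -2.25 for CG4511, -9.22 for moody, -0.86 for CG15725 and -1.03 for CG32512. Among the 5479 probe sets outside the series matrix, 24 were higher and 16 lower in C17 and 24 higher and 21 lower in PMdr65 against all 3 control groups.

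The third WT_new array and the second UAS_control array stood apart from their groups. Among eye genes under a mean log2 signal of 10 on the other WT_new arrays, WT_new array 3 was higher by a median of 3.56, and muscle genes on UAS_control array 2 were higher by 2.52 than on the other UAS_control arrays; the same eye genes were also higher on all UAS_control arrays, by 1.88, 3.39 and 2.92. The first form of the eye test, over all 17 members, gave 0.12 and met its condition against eye RNA; it was changed after that value was seen, because 7 members were high in every brain and shifted by -0.22 to 0.12. A scaling error stays undecided: neuronal genes moved by -0.05 on each array, which on WT_new array 3 was -1.4 percent of the shift of the eye genes so chosen, but RMA sets the arrays to a common level and so largely fixed this outcome. The values are consistent with eye and muscle tissue in these samples, as a hypothesis found and tested on the same data, and no biological explanation was tested.

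The wild-type groups differed in 6035 probe sets. Eye or muscle RNA in single arrays was argued against as the main cause, since 5335 probe sets were called without both arrays. Relative to WT_new arrays 1 and 2, the dimmer eye genes tested above had medians of -0.87 to -0.61 on the WT_old arrays. Those on the mutant arrays were -1.01 to -0.69. Eye RNA at a lower level on every WT_new array was not tested and stays open, also in the next comparison. Of the 1000 probe sets with the largest difference between WT_old and WT_new array 1, 83.1% had both mutants on the WT_old side of WT_new array 2, as a processing batch of WT_new may produce, and 46.1% had UAS_control there. Differences of age, culture and processing day between the wild-type groups were not tested and stay open, and batch and group cannot be told apart against WT_new.

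The changes shared by both mutants may come from linked background, from variants under single probes or from the alleles. Both genes of 20 neighbouring pairs were called, against a mean of 11.2 and a highest count of 25 in 10000 random reassignments (one-sided permutation test, p = 0.0087), short of the 2-fold excess set in advance. For C17 alone 66 pairs exceeded every reassignment (mean 39.2, highest 65), so its called genes lay beside each other more often than by chance, while PMdr65 had 87 (mean 73.2, highest 104). Of 48 other probe sets of these genes 35.4% moved the same way in all 6 contrasts (95% interval 22.2 to 50.5), against 27.6% of all second probe sets. Neither test decides for the shared genes, and the shared background of the mutants, which UAS_control only resembles, stays open beside an effect of the alleles.

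Other splits of the arrays gave as many calls in 1 split each, the real one. With 10 splits they are too few for a share under 0.05: the real counts and the highest others were 5449 and 0 for C17 and 5523 and 0 for PMdr65 against WT_new, 5736 and 0, and 5262 and 0 against UAS_control, 937 and 1 for C17 against PMdr65, and 2015 and 585 for UAS_control against WT_new. With 56 splits the real one alone gave as many calls, a share of 0.018. This held for C17 (2612, highest other 32) and PMdr65 (3847, 84) against WT_old. It also held for WT_old against WT_new (6035, 285) and UAS_control against WT_old (7365, 254). That share is the smallest that 56 splits can give. It takes the arrays as independent samples, which the labels do not state, so chance is not excluded. With 100 drawn no other split gave as many calls against all 3 control groups in C17 (858, 76), PMdr65 (1109, 316) or both (426, 0). These draws also mixed the control groups, which differ from each other. Such mixing widens the spread within the drawn groups, so low counts were largely fixed in advance and the draws cannot decide on chance.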

How the results depend on the processing

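Leaving out WT_new array 3 and UAS_control array 2 was chosen after the data were seen, and leaves eye RNA on the other UAS_control arrays. With other probe sets compared in only 1 contrast per named result, 1076 values of named genes kept direction and call, 81 lost the call and 1 reversed: another probe set of Nrg gave -0.20 in PMdr65 against WT_new. In further contrasts another probe set of ftz-f1 gave 0.55 and 0.72 against WT_new, where the gene fell, and 1 of Rim gave -0.37 in C17, where the gene was at 0.35; the causes were not tested. The oxidative phosphorylation list reversed against WT_old (adjusted p = 0.021 in C17 and 0.0042 in PMdr65; adjusted p = 0.71 and 0.65 with an estimated correlation). Signal over background limits the dim genes. A limit of 2-fold left, by its construction, 448 and 516 probe sets for C17 and PMdr65 against WT_new, 296 and 348 against WT_old, 653 and 552 against UAS_control, 174 between the mutants, 292, 294 and 808 for WT_old against WT_new, UAS_control against WT_new and UAS_control against WT_old, and 84, 71 and 18 for C17, PMdr65 and both against all 3 control groups. Pooled wild types gave 1699 (C17) and 2461 (PMdr65). Array weights gave 4553 for C17 against WT_old, 2335 between the mutants and 1228 for UAS_control against WT_new. Fits of only the groups compared gave 1637 between the mutants and 488 for UAS_control against WT_new, and without the dimmest 40% the latter was 1241. Leaving out single arrays gave 1709 (without C17 array 2) to 2587 for C17 against WT_old, 601 (C17 array 3) to 671 between the mutants, 1219 (WT_new array 1) to 2404 for UAS_control against WT_new, 553 (C17 array 2) to 867 for C17 against all 3 control groups and 283 (C17 array 2) to 436 for both mutants. Lists lost their call against WT_new with an estimated correlation, with adjusted p = 0.54 in C17 (septate junctions, ribosomal proteins, oxidative phosphorylation) and in PMdr65 0.064 (septate junctions) and 0.68 (odorant binding, ribosomal proteins, oxidative phosphorylation). With WT_old as the control, ribosomal proteins gave 0.43 and 0.88 and odorant binding proteins 0.35; the latter gave 0.21 without dim probe sets and 0.15 when 1 array was left out. Of 60 list results against WT_new, 27 not called by camera were called in the same direction by fry, 8 with WT_old and 8 with UAS_control as the control; further ones were called in the opposite direction. The causes were not tested. Replicate numbers did not pair the arrays (4 of 30 correlations of deviations over 0.1, median 0), and with the number as a replicate block the calls were 5119 and 5160 against WT_new, 1911 and 2922 against WT_old, 5484 and 4910 against UAS_control, 790 between the mutants, 678 and 910 against all 3 control groups and 330 in both; septate junction members higher in C17 against all 3 control groups went from 5 to 2.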

Other observations

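The tests of surface glia, of neighbouring genes and of chromosomes were chosen after the results were seen.

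Of 64 measured genes of chromosome 4, 13 rose and 0 fell in PMdr65 against all 3 control groups (20.3%; Fisher's exact test, adjusted p = 0.021), and 9 rose and 0 fell in C17 (14.1%; adjusted p = 0.095, which did not pass). The 7 genes called in both were CG31999, Hcf, Kif3C, Sox102F, ci, myo and zfh2, of which ci, a transcription factor of hedgehog signalling, rose by 0.71 to 1.59 on the log2 scale in C17 and 0.81 to 1.70 in PMdr65. The chromosome's median log2 fold change was 0.28, 0.11 and 0.24 in C17 and 0.28, 0.13 and 0.27 in PMdr65 against WT_new, WT_old and UAS_control, and 0.20 in WT_old against WT_new. On the X chromosome 61 of 1463 genes were called in C17 (4.2%; adjusted p = 0.00028), against 6.6% of all genes, and in PMdr65 122 were (8.3%; adjusted p = 0.44). On the right arm of chromosome 2 the share was 8.2% in C17 (150 of 1828; adjusted p = 0.014) and 89 genes were called in both mutants (4.9%; adjusted p = 0.0074).

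A rise of moody in PMdr65 could come from more surface glia in these brains. The 19 other surface glia genes then had to rise too. Their median was 0.12 against UAS_control (quartiles -0.28 to 0.48), 0.44 against WT_new and 0.66 against WT_old. The smallest rise of moody was 1.37, so the list as a whole rose less. However, 7 of the 19 genes were called higher against every control group, among them Gli, Lac, ltl and CG10226. The list also holds Col4a1, trol and vkg, which are in the extracellular matrix list too. Its median therefore cannot decide on more surface glia.

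The lesion of moody may affect neighbouring genes: 4 of the 10 nearest measured genes were called in C17 (CG4325, Sik2, CG14054 and CG4194), as many as in 1.0% of 1453 windows on the chromosome. For Mdr65 the count was 1 (CG10226), reached in 61.2% of 1703 windows, so the test does not decide for both alleles.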
